A study of Mus musculus with 15 samples.

How the data were processed

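Skin of C57BL/6 mice was sampled at day 0, 1, 3, 5 and 7 of a wounding time course, with 3 libraries per time and 15 in all. Per the labels' protocols, the skin was freed of muscle and fat and frozen, total RNA was extracted, and libraries were prepared with the VAHTS mRNA-seq V2 kit, which selects polyadenylated RNA. Sequencing was on a HiSeq X-Ten, per the labels. The labels carry the wound stress for every library, day 0 included, so the first group is called day 0 throughout. Nothing in the labels says that the 3 libraries of a time came from separate animals, so p-values measure only the spread between these samples, which may be technical.

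The values deposited by the authors are estimated counts per gene symbol, 1 file per library, made with kallisto 0.43 per the submitters' processing notes. The transcript index, the gene annotation, the genome build and the step from transcripts to genes are not given in the sources used here. For that reason no genome coordinates are printed, and a mouse annotation (GENCODE M21) served only to tell gene types and which genes neighbour each other. The estimated counts were whole numbers as deposited and were passed through rounding without change. Pseudoalignment shares a read among transcripts it matches equally well, so genes with a near-identical copy (Saa1 and Saa2, the Sprr2a genes, Krt6a and Krt6b, Stfa2l1, Eno1 and Eno1b, Ifi208, Mup17, H2-T10 and H2-T24) have uncertain values. Whether strand was used in counting is not given either, so overlapping and antisense genes cannot be told apart. Each file held 30307 rows. In each library 26 of them carried calendar dates in place of gene symbols, as a spreadsheet makes of the Marchf and Septin gene names, and these were left out. They held 0.155% to 0.179% of the counts. The library totals ran from 38062562 to 60450396 estimated counts. At that depth counting error is small beside the spread between replicates, which the fitted common biological coefficient of variation put at 30.9%.

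All tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by edgeR's expression filter with a minimum count of 10, which left 17136 of 30281 named genes. Library sizes were scaled by the trimmed mean of M-values (TMM). One quasi-likelihood model with the 5 times as groups and robust dispersion was fitted over all 15 libraries. Contrasts gave each wounded time against day 0 and each time against the time before it, and an F test of all 4 differences from day 0 gave the genes changed over time. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and a gene was called at an adjusted p under 0.05. P-values of contrasts between times and of lists tested one way are two-sided. The F test over all times and the mixed list test have no direction. The permutation p of neighbouring genes, given below, counts the upper tail alone. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values (counts relative to the library total) are scaled by the same library sizes and are given as mean ± SD over 3 libraries. The median log2 fold change over all genes stayed within 0.0167 of 0 in each comparison.

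Gene lists for cell types, tissue structures and pathways of healing skin, 33 of them, were tested with fry on voom values, a rotation test of whether a list's genes move on balance one way, with Benjamini-Hochberg adjustment over the lists of a comparison. A mixed form of the same test asks whether members change in either direction. Neither compares a list with other genes. Camera, which does, was run with a correlation between genes estimated from the data and with a preset correlation of 0.01. For each list the members called over all genes are counted, and those called when p-values are adjusted over the list alone. Of 590 genes in the lists, 586 were in the files. A further list of sex-linked genes checked the samples. The Y-linked Ddx3y was present at 91.1 to 124 CPM in all 15 libraries.

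The groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined. For each comparison with day 0 the rule takes the 8 called genes with the highest and the 8 with the lowest fold change, and for the others 4 of each. These genes are changed at least 2-fold, reach a mean of 5 CPM in the higher group, have ordinary symbols and show no overlap between the libraries of both groups. Per list it takes up to 4 called members with the largest change, or, where none was called, up to 2 with the smallest p. It also takes 17 genes followed through all times and the 4 genes with the widest range for each time of highest mean. Not all genes the rule allows are named, and which of them to describe was chosen after the values were seen. Genes named outside it are said to be. Results of some called genes are not reported here.

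Replicates carry the numbers 1 to 3 at each time, with no label saying what a shared number means. Deviations from the group means were correlated between libraries of the same number. For day 7 against day 0 all 3 correlations were over 0.1 (0.144, 0.131 and 0.406), which does not show that the numbers pair these samples. For day 7 against day 5 they were 0.288, -0.588 and -0.729. Of the 15 libraries, 4 had their best match outside their group in a library of their own number. The main fit therefore leaves the number out. A fit with the number as a block called 822 genes there against 1208 without it, and kept the list call made there at a fry adjusted p of 0.0441. In each of the other comparisons at least 1 correlation was under 0.1.

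No pair of libraries was alike within sampling noise. The lowest chi-square per degree of freedom between any 2 libraries was 33.2. The pipeline was tested on simulated counts for all 15 libraries, built from each gene's mean over all of them and their library sizes. At day 1, 200 of 16978 genes were changed. In day 1 against day 0 the pipeline recovered 48% of genes changed 2-fold and 82.8% of those changed 4-fold. It made 11 false calls (7.8% of its calls), and called 0 genes in a comparison with no change. Fry called a simulated list of raised genes and did not call a list of unchanged genes. Genes were drawn independently and no simulated library stood apart, so these rates may not hold for the data. Lists of correlated genes were not covered.

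Alternatives were DESeq2 1.42.0 as the test, DESeq2 size factors, no low-count filter, a stricter filter of 5 CPM in 3 libraries, a replicate block, removal of muscle, fat and blood genes, a fit of only the 6 libraries compared, a minimum of 2-fold change, and each library left out in turn. Added after seeing the data were removal of day 5 replicate 2 and day 7 replicate 3, removal of these with day 0 replicate 1, a hair follicle covariate, and a fit with day 0 replicate 1 as the only day 0 library.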

Results

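RNA was sequenced from mouse skin at 5 times of a wounding course, day 0, 1, 3, 5 and 7, to follow gene expression as the skin healed. The mice were of the C57BL/6 strain. Each time had 3 libraries, and each library held between 38062562 (day 7 replicate 2) and 60450396 (day 5 replicate 1) estimated counts. After removal of weakly expressed genes, 17136 genes were tested. The first principal component held 38.7% of the variance between libraries and the second 18%.

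Mitochondrial genes took 5.29% to 6.30% of the counts in the day 0 libraries, 6.98% to 7.53% at day 1, 5.34% to 6.30% at day 3, 7.42% to 8.70% at day 5 and 8.09% to 9.44% at day 7, so at day 1, 5 and 7 each library lay above the day 0 libraries. Several libraries stood apart from the others of their own time. Hair follicle genes, mostly hair keratins, took 2.04% of the counts in day 5 replicate 2 and 2.28% in day 7 replicate 3, against at most 0.222% in each of the other 13 libraries. Wound-response genes were high in day 0 replicate 1, where the keratin Krt6a stood at 708 CPM and the cytokine Il1b at 86.1 CPM, against 54.3 and 95.2 CPM of Krt6a and 13.8 and 12.9 CPM of Il1b in day 0 replicates 2 and 3. Day 0 replicates 2 and 3 in turn differed from all other libraries in 42 genes by at least 4-fold, 28 higher and 14 lower, and the genes named next were chosen after their values were seen. Skint3, of a family of epidermal membrane proteins, was at 0.278 and 0.218 CPM there, at 93.1 CPM in day 0 replicate 1 and at 38.5 to 154 CPM in the 12 libraries of the later times. Eno1b, a near-identical copy of the enolase gene Eno1, was at 123 and 150 CPM there and at or below 0.294 CPM elsewhere.

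**Figure D1:**
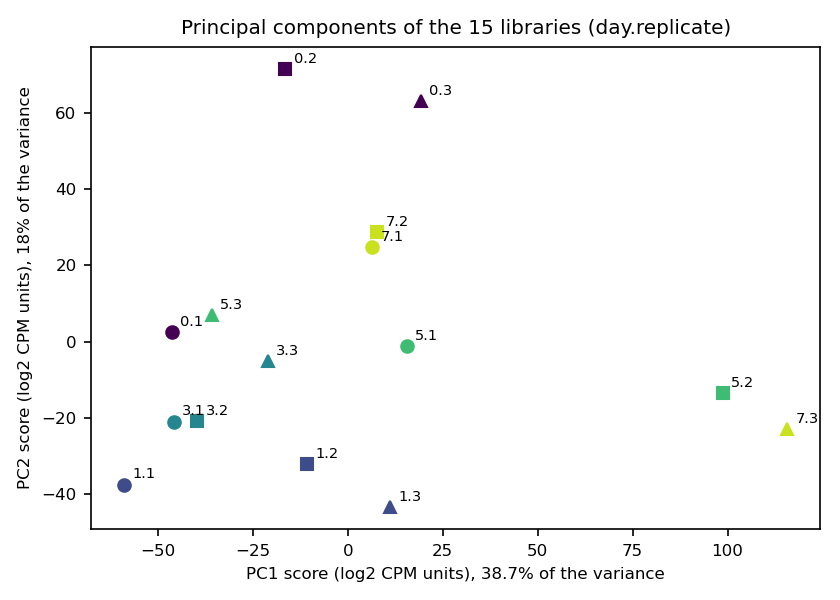
Principal component scores of the 15 libraries, in log2 CPM units, with the day as colour and the replicate number as marker shape (each point labelled day.replicate). Day 5 replicate 2 and day 7 replicate 3 lie at 98.71 and 115.73 on the first component, and day 0 replicates 2 and 3 at 71.48 and 63.02 on the second, where day 0 replicate 1 is at 2.54.

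**Figure D2:**
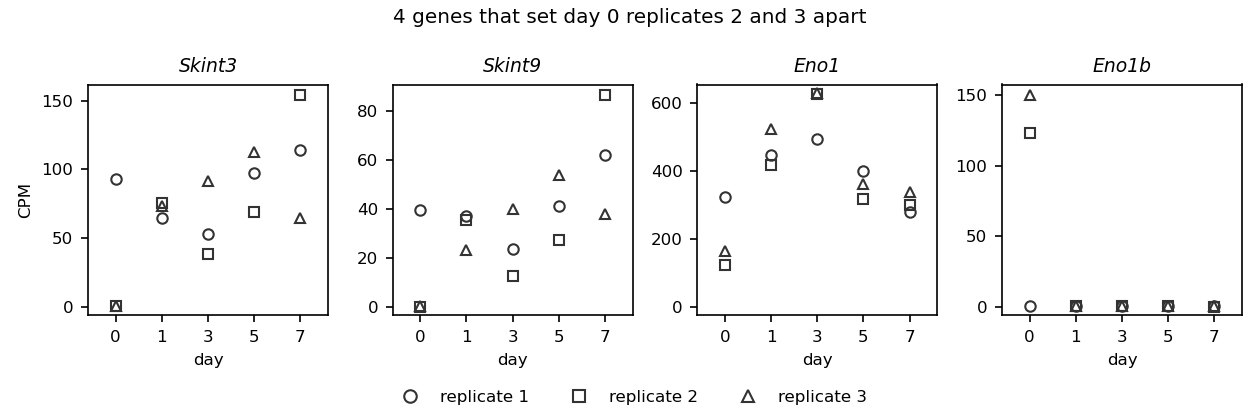
CPM of Skint3, Skint9, Eno1 and Eno1b in each of the 15 libraries by day, on linear axes, with the replicate number as marker shape. Day 0 replicates 2 and 3 lie near 0 for Skint3 and Skint9 and are the only libraries with Eno1b above 0.294 CPM.

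The comparison of day 1 with day 0 addresses the earliest response sampled. At day 1, lists of neutrophil, cytokine, hypoxia and glycolysis, growth factor, wound-edge keratinocyte and protease genes rose, and a list of T and NK cell markers fell. Tested against other genes by camera, the 7 calls were lost with an estimated correlation (adjusted p = 0.327 for neutrophils and 0.458 for the other 6) and made with a preset one (adjusted p = 2.64e-12 to 0.00462). S100a9, a calcium-binding protein abundant in neutrophils, rose 12.9-fold, from 43.9 ± 41.1 to 567 ± 149 CPM (SD, n = 3). Il6, an inflammatory cytokine, rose by 3.59 ± 0.64 (SE) on the log2 scale, from 1.86 ± 1.96 to 22.5 ± 10.8 CPM, and Ptx3, a soluble pattern recognition protein, rose 18.8-fold, from 5.97 ± 2.79 to 113 ± 6.34 CPM. Clec3b, a marker of resting fibroblasts, fell 4.09-fold, from 608 ± 215 to 149 ± 36.8 CPM.

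In all, 1299 genes differed between day 1 and day 0 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 723 higher and 576 lower at day 1, and 258 and 294 of these by at least 2-fold. Saa2 and Saa1, acute-phase proteins with near-identical sequences whose values are uncertain, rose by 5.59 ± 1.27 (SE) and 5.02 ± 0.86 on the log2 scale. Fgf23, a hormone of phosphate balance, rose by 5.46 ± 1.18 (edgeR adjusted p = 0.0211), Csf3, the granulocyte colony-stimulating factor, by 4.50 ± 0.99 (edgeR adjusted p = 0.0218), and Mrgpra2b, a receptor of the Mas-related family, by 3.76 ± 0.93. Sult1e1, an estrogen sulfotransferase, fell by 5.78 ± 1.33 (edgeR adjusted p = 0.0259). The signalling protein Wnt2 fell by 3.52 ± 0.71, Angptl7 by 3.33 ± 0.83 and the methyltransferase Inmt by 3.21 ± 0.72. Ifi208 fell by 3.73 ± 0.77, but was at 1.10 CPM in day 0 replicate 1 and at 17.9 and 18.9 CPM in replicates 2 and 3, so its fall rests on the day 0 libraries that stood apart.

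Of 18 neutrophil markers, 11 rose and 7 did not pass, and 14 rose when adjusted over the list alone (fry adjusted p = 0.000851, and adjusted p = 0.327 with an estimated correlation). Ly6g rose by 4.25 ± 0.95 on the log2 scale, S100a8 by 3.23 ± 0.77 and the chemokine receptor Cxcr2 by 3.53 ± 0.79. Stfa2l1, whose close copies leave its value uncertain, rose by 4.65 ± 1.20. Of 22 inflammatory cytokines and chemokines, 7 rose and 15 did not pass, while 19 rose and 1 fell when adjusted over the list alone (fry adjusted p = 0.00637, and adjusted p = 0.458 with an estimated correlation). Il19 rose by 4.01 ± 0.76, the neutrophil attractant Cxcl3 by 3.73 ± 0.87 and Osm by 2.83 ± 0.69. Il1b had 307 ± 122 CPM at day 1 against 37.6 ± 42.0 at day 0 and did not pass (edgeR adjusted p = 0.0594). Both lists were highest at day 0 in replicate 1, where the mean of the neutrophil list lay at 0.69 on the log2 scale against the day 0 mean, and at -0.62 and -0.07 in replicates 2 and 3. The cytokine list lay at 1.30 there and at -0.80 and -0.50 in replicates 2 and 3, with a day 1 mean of 2.65.

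Of 22 hypoxia and glycolysis genes, 10 rose and 12 did not pass, and 12 rose when adjusted over the list alone (fry adjusted p = 0.00802, and adjusted p = 0.458 with an estimated correlation). The vasoactive peptide gene Adm rose by 2.92 ± 0.74, the lactate transporter Slc16a3 by 1.22 ± 0.16, and the glucose transporter Slc2a1 by 1.22 ± 0.22. Eno1 rose by 1.18 ± 0.27, but was at 323 CPM in day 0 replicate 1 and at 123 and 165 CPM in replicates 2 and 3. Its near-identical copy Eno1b was present in day 0 replicates 2 and 3 alone. Reads given to the copy may therefore lower Eno1 there, and the size of its rise is uncertain. Another called member, Gapdh, chosen after its values were seen, was at 923, 372 and 384 CPM in day 0 replicates 1, 2 and 3. Of 21 growth factors of repair, 4 rose, 1 fell and 16 did not pass, and 8 rose and 1 fell when adjusted over the list alone (fry adjusted p = 0.012, and adjusted p = 0.458 with an estimated correlation). Besides Csf3, the activin subunit Inhba rose by 1.35 ± 0.35 and Hgf by 1.01 ± 0.25, while Tgfb2 fell by 1.49 ± 0.37.

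Of 21 wound-edge keratinocyte genes, 3 rose and 18 did not pass, and 7 rose when adjusted over the list alone (fry adjusted p = 0.0268, and adjusted p = 0.458 with an estimated correlation). The protease inhibitor Slpi rose by 2.76 ± 0.76, the urokinase receptor Plaur 2.84-fold and the laminin chain Lama3 by 1.16 ± 0.31. The stress keratins Krt6a and Krt16 had 1418 ± 593 and 596 ± 268 CPM at day 1 against 286 ± 366 and 141 ± 199 CPM at day 0, and did not pass (edgeR adjusted p = 0.084 and 0.145). Of 18 matrix proteases and inhibitors, 5 rose, 1 fell and 12 did not pass, and 9 rose and 3 fell when adjusted over the list alone (fry adjusted p = 0.0278, and adjusted p = 0.458 with an estimated correlation). The inhibitor Timp1 rose by 1.85 ± 0.51, and the proteases Adamts1, Mmp9 and Adamts4 rose by 1.57 ± 0.32, 1.33 ± 0.34 and 1.03 ± 0.23. Timp3, named after its values were seen, fell by 0.78 ± 0.14. In day 0 replicates 1, 2 and 3 the mean of the wound-edge list lay at 1.20, -0.79 and -0.40 (day 1 mean 1.74) and that of the protease list at 0.68, -0.46 and -0.23 (day 1 mean 1.13).

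Of 16 T and NK cell markers, 5 fell and 11 did not pass, and 13 fell when adjusted over the list alone (fry adjusted p = 0.0373, and adjusted p = 0.458 with an estimated correlation). Nkg7 fell by 1.89 ± 0.44, Cd2 by 1.64 ± 0.41, and the T cell receptor chains Cd3e and Cd3d by 1.48 ± 0.37 and 1.37 ± 0.30. Of 12 dendritic and Langerhans cell markers, 4 fell and 8 did not pass, and 5 fell when adjusted over the list alone, with the list itself not called (fry adjusted p = 0.0997). Among them the antigen presentation genes H2-Eb1 and Cd74 fell by 1.61 ± 0.36 and 1.58 ± 0.33. Of 9 B and plasma cell markers, 3 fell, also when adjusted over the list alone, and the list was not called (fry adjusted p = 0.0865). Ighm fell by 1.93 ± 0.37 and Jchain by 2.73 ± 0.71. Of 15 fibroblast markers 5 fell, among them Pi16, Dpp4 and Cd34 by 1.69 ± 0.46, 1.44 ± 0.25 and 1.32 ± 0.31, while 1 rose. Adjusted over the list alone, 6 fell and 1 rose (fry adjusted p = 0.25, mixed test adjusted p = 0.000569).

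Of 12 genes of alternative macrophage activation 3 rose, and 3 rose and 3 fell when adjusted over the list alone. Chil3 rose by 3.17 ± 0.79, the arginase Arg1 by 1.94 ± 0.49 and the receptor Il4ra by 1.82 ± 0.25. The list's median was -0.34 and its mean -0.18, while the fry test pointed up (adjusted p = 0.887, mixed test adjusted p = 0.000142). Of 28 extracellular matrix genes 4 rose and 2 fell, and 8 rose and 6 fell when adjusted over the list alone (fry adjusted p = 0.887, mixed test adjusted p = 0.000569), with Thbs1 and Tnc up by 2.23 ± 0.50 and 1.92 ± 0.53. Before TMM scaling Tnc was at 257 CPM in day 0 replicate 1 and at 41.3 and 68.6 CPM in replicates 2 and 3. Of 26 cell cycle genes 8 rose, and 10 when adjusted over the list alone, with the list not called (fry adjusted p = 0.153). Among them the replication gene Mcm6 and the cyclin Ccne2 rose by 0.86 ± 0.19 and 1.08 ± 0.29. Of 20 endothelial genes 2 rose, and 3 when adjusted over the list alone (fry adjusted p = 0.253). These were Apln, by 1.52 ± 0.29, and Angpt2, by 0.99 ± 0.15. The clock genes Npas2 and Arntl fell by 1.19 ± 0.27 and 0.88 ± 0.12.

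The count of 1299 was 2411 without day 0 replicate 1, 33 and 142 without day 0 replicates 2 and 3, and 137, 312 and 426 without day 1 replicates 1, 2 and 3. With day 0 replicate 1 as the only day 0 library, edgeR called 0 genes, with 1324 at an unadjusted p under 0.05, while DESeq2 on all libraries called 2786. Of the 60 genes named as called, 4 (Arntl, Il4ra, Ptx3 and Slc16a3) were called with each of the 6 libraries left out in turn. The neutrophil, cytokine and hypoxia and glycolysis lists were called in each of these 6 fits. The growth factor list was not called without day 0 replicate 2 (fry adjusted p = 0.0576). The T and NK cell list was not called without day 0 replicates 2 and 3 (0.0695 and 0.103) or day 1 replicates 1, 2 and 3 (0.0761, 0.0764 and 0.117). The wound-edge list was not called without day 0 replicates 2 and 3 (0.108 and 0.103) or day 1 replicates 1 and 3 (0.0761 and 0.0805). The protease list was not called without day 0 replicates 2 and 3 (0.112 and 0.103) or day 1 replicates 1, 2 and 3 (0.0761, 0.0531 and 0.0607).

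**Figure D3:**
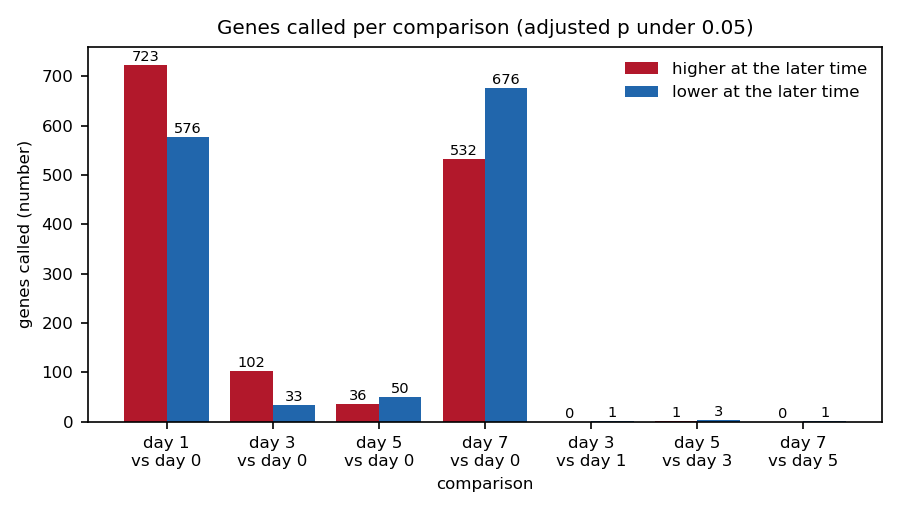
Number of genes called at an adjusted p under 0.05 (edgeR) in each comparison, with bars from 0, red for genes higher and blue for genes lower at the later time. Day 1 and day 7 against day 0 gave 1299 and 1208 genes, and day 3 and day 5 against day 0 gave 135 and 86.

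**Figure D4:**
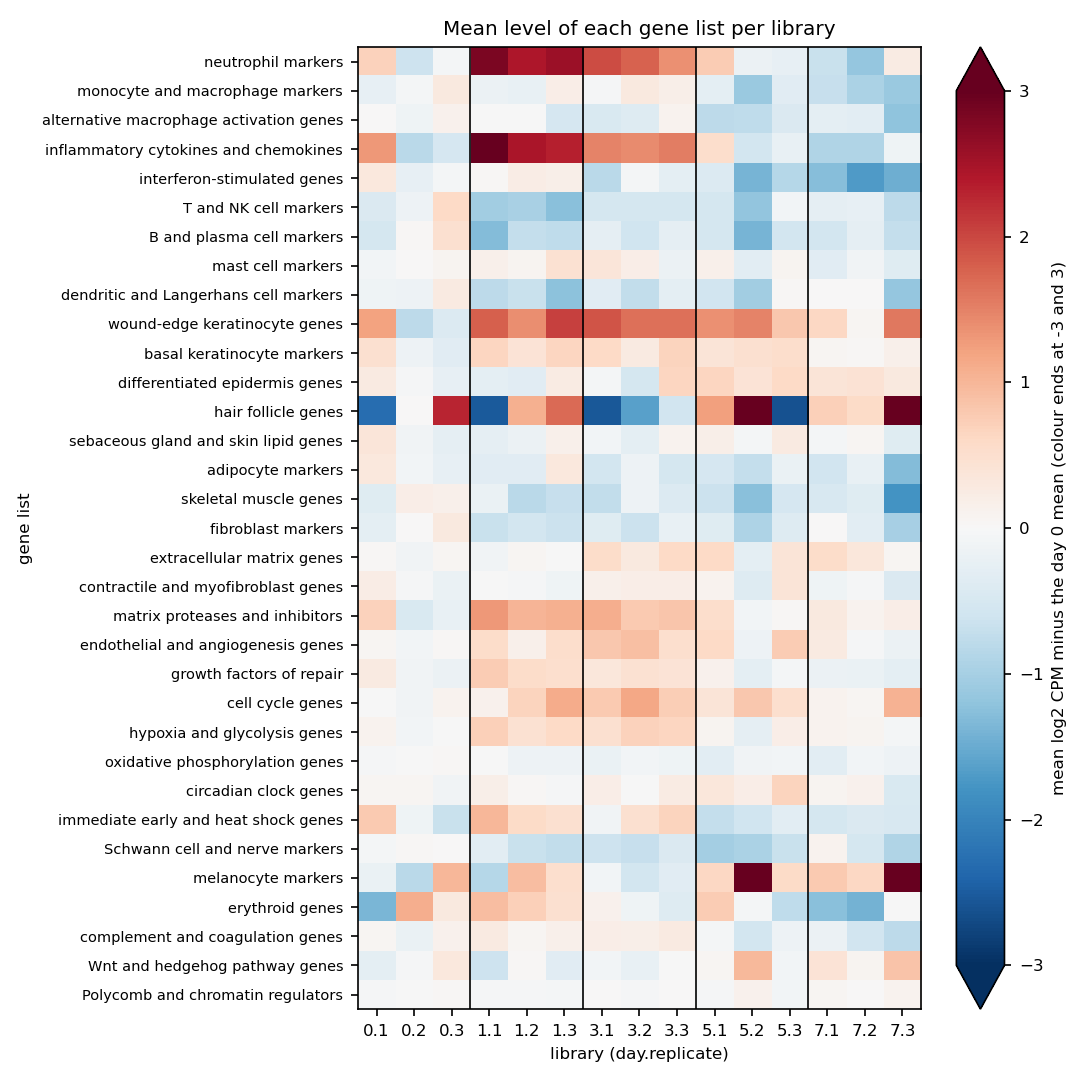
Mean log2 CPM of each of the 33 gene lists in each of the 15 libraries, minus the mean of the list at day 0, as a colour scale that ends at -3 and 3, with columns labelled day.replicate. The neutrophil list averaged 2.61 at day 1 and 1.70 at day 3, and the interferon-stimulated list -1.48 at day 7, while the hair follicle list reached 5.29 in day 5 replicate 2 and 5.48 in day 7 replicate 3.

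The comparison of day 3 with day 0 addresses the skin after the first days of repair. At day 3, lists of hypoxia and glycolysis genes and of neutrophil markers were raised, and single genes of keratinocytes, matrix and blood vessels rose. Tested against other genes by camera, both list calls were lost with an estimated correlation (adjusted p = 0.246 and 0.357) and made with a preset one (adjusted p = 4.99e-13 and 6.8e-09). Krt14, the keratin of basal keratinocytes, rose 3.66-fold, from 1380 ± 724 to 5044 ± 805 CPM (SD, n = 3). Apln, a peptide of sprouting vessels, rose 4.13-fold, from 6.75 ± 1.18 to 27.9 ± 8.45 CPM, and Arg1 6.31-fold, from 14.9 ± 3.09 to 94.0 ± 29.4 CPM. Timd4, a receptor of resident macrophages, fell 6.45-fold, from 8.19 ± 1.05 to 1.27 ± 0.405 CPM.

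By edgeR 135 genes differed, 102 higher and 33 lower at day 3, and 68 and 26 of these by at least 2-fold. The epidermal barrier genes Sprr2a3 and Sprr2a1, close copies with uncertain values, rose by 4.16 ± 0.78 and 3.46 ± 0.67 on the log2 scale. The serine protease Tmprss11g rose by 3.67 ± 0.61 (edgeR adjusted p = 0.0334), Kng2 by 3.19 ± 0.65 and the threonine dehydrogenase Tdh by 2.82 ± 0.56. The hyaluronan-degrading protein Cemip rose by 3.42 ± 0.64, from 3.30 CPM in day 0 replicate 1 and 0.810 and 1.15 CPM in replicates 2 and 3. Among the falls were Smpd3 by 1.63 ± 0.28, Igfbp6 by 1.59 ± 0.32 and the macrophage lectin Cd209g by 1.73 ± 0.36. Ifi208 fell by 3.89 ± 0.78 and H2-T10, a class I histocompatibility gene with close copies, by 2.05 ± 0.41, but both were low in day 0 replicate 1 (1.10 and 9.12 CPM) and high in replicates 2 (17.9 and 34.0 CPM) and 3 (18.9 and 36.0 CPM).

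Of 22 hypoxia and glycolysis genes, 6 rose and 16 did not pass, and 11 rose when adjusted over the list alone (fry adjusted p = 0.00736, and adjusted p = 0.246 with an estimated correlation). Slc2a1 rose by 1.29 ± 0.22, Slc16a3 by 0.96 ± 0.16 and the oxygen sensor Egln3 by 0.84 ± 0.15. Eno1 rose by 1.52 ± 0.28, which is uncertain for the same reason as at day 1, the copy Eno1b in day 0 replicates 2 and 3. Of 18 neutrophil markers, 2 rose and 16 did not pass, and 11 rose and 1 fell when adjusted over the list alone (fry adjusted p = 0.0271, and adjusted p = 0.357 with an estimated correlation). These were the collagenase Mmp8, by 2.49 ± 0.41, and the receptor Csf3r, by 1.30 ± 0.25, while S100a8 stood at 202 ± 60.6 CPM against 27.3 ± 17.1 and did not pass (edgeR adjusted p = 0.1). Of 20 endothelial genes, 3 rose and 17 did not pass, and 11 rose and 1 fell when adjusted over the list alone, without a list call (fry adjusted p = 0.0941). Besides Apln, its receptor Aplnr rose by 1.72 ± 0.34 and Angpt2 by 1.02 ± 0.15. Of 28 extracellular matrix genes, 2 rose, the collagen Col12a1 by 2.07 ± 0.40 and the prolyl hydroxylase P4ha3 by 1.73 ± 0.32, and 10 when adjusted over the list alone (fry adjusted p = 0.188).

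Of 26 cell cycle genes edgeR called 0 over all genes, and 22 rose when adjusted over the list alone, with the list not called (fry adjusted p = 0.0931). Mki67, a marker of dividing cells, had 129 ± 7.42 CPM against 70.5 ± 7.50 (edgeR adjusted p = 0.226). Of 21 wound-edge keratinocyte genes edgeR called 0, and 10 rose when adjusted over the list alone (fry adjusted p = 0.0533). Krt6a had 2220 ± 199 CPM at day 3 and Krt16 1070 ± 35.6 CPM (edgeR adjusted p = 0.108 and 0.142), and in day 0 replicate 1 they were at 708 and 371 CPM against at most 95.2 and 31.3 CPM in replicates 2 and 3. Of 12 Schwann cell and nerve markers 1 fell, S100b, by 1.09 ± 0.21, and 4 when adjusted over the list alone (fry adjusted p = 0.122). Arntl fell by 0.96 ± 0.12 and Timp3 by 0.73 ± 0.14.

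The count of 135 was 629 without day 0 replicate 1, 59 without day 3 replicate 3, and 0 without day 0 replicate 2 or 3 or day 3 replicate 1 or 2, where 1617, 2079, 2049 and 1954 genes had an unadjusted p under 0.05 by edgeR. With day 0 replicate 1 as the only day 0 library edgeR called 0 genes, with 1051 at an unadjusted p under 0.05, and DESeq2 on all libraries called 943. The hypoxia and glycolysis list was called with each of the 6 libraries left out in turn. The neutrophil list was not called without day 0 replicates 2 and 3 (fry adjusted p = 0.108 and 0.13) or day 3 replicates 1 and 2 (0.103 and 0.077).

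The comparison of day 5 with day 0 addresses mid repair. At day 5 fry called 0 of 33 lists one way and 9 by its mixed form (camera 0 with an estimated and 16 with a preset correlation), and single genes changed, among them lower Schwann cell and macrophage genes and higher matrix genes. Mbp, the myelin basic protein, fell 3.66-fold, from 172 ± 9.49 to 46.9 ± 11.3 CPM (SD, n = 3). The macrophage lectin Cd209f fell 5.27-fold, from 108 ± 4.62 to 20.5 ± 7.04 CPM. Tnn, a tenascin of the matrix, rose 6.17-fold, from 7.26 ± 2.01 to 44.8 ± 22.5 CPM.

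By edgeR 86 genes differed, 36 higher and 50 lower at day 5, and 25 and 35 of these by at least 2-fold. Fetub, a fetuin, rose by 4.07 ± 0.73 on the log2 scale (edgeR adjusted p = 0.0426), Tdh by 2.99 ± 0.56, Serpina9 by 2.72 ± 0.43, Hhipl1 by 2.25 ± 0.39 and the kinesin Kif26b by 2.04 ± 0.35. Timd4 fell by 3.39 ± 0.48 and Cd209g by 2.68 ± 0.37. Ifi208 fell by 4.03 ± 0.79, with 1.10 CPM in day 0 replicate 1 and 17.9 and 18.9 CPM in replicates 2 and 3. Of 12 Schwann cell and nerve markers, 3 fell and 9 did not pass, and 8 fell when adjusted over the list alone. The list was not called one way (fry adjusted p = 0.108) but was by the mixed test (adjusted p = 0.000619, and adjusted p = 0.672 one way with an estimated correlation). Among them the Schwann cell genes Prx and Mbp fell by 1.96 ± 0.37 and 1.87 ± 0.35, and outside the list Cldn19, Pmp2 and Ncmap fell by 2.56 ± 0.35, 2.46 ± 0.36 and 2.24 ± 0.38.

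Of 28 extracellular matrix genes, 2 rose, Col12a1 by 2.16 ± 0.40 and P4ha3 by 1.63 ± 0.32, and 4 when adjusted over the list alone (fry adjusted p = 0.574). Of 19 monocyte and macrophage markers 1 fell, the integrin Itgam, by 1.15 ± 0.22, and 6 when adjusted over the list alone (fry adjusted p = 0.271). Of 18 interferon-stimulated genes 1 fell, Usp18, by 1.26 ± 0.25, and 11 when adjusted over the list alone (fry adjusted p = 0.108). Of 16 clock genes, Per2 rose by 1.88 ± 0.37 and Npas2 and Arntl fell by 1.49 ± 0.27 and 1.07 ± 0.12, and 8 rose and 3 fell when adjusted over the list alone (fry adjusted p = 0.434, mixed test adjusted p = 0.000215). The immediate early gene Dusp1 fell by 2.04 ± 0.38, Angpt2 rose by 0.88 ± 0.15 and Egln3 by 0.74 ± 0.15. Arg1 had 71.0 ± 24.1 CPM against 14.9 ± 3.09 and Krt6a 1181 ± 164 against 286 ± 366, and neither passed (edgeR adjusted p = 0.0614 and 0.186). The 24 hair follicle genes had a median log2 difference of 2.89, edgeR called 0 of them, and the list did not pass (fry adjusted p = 0.696). Their mean lay at 1.23, 5.29 and -2.61 in the 3 day 5 libraries.

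The count of 86 (36 higher, 50 lower) turned to mostly higher, 63 and 12, without day 5 replicate 2, and to 177 and 129 without both hair-rich libraries. It was 495 (253 higher, 242 lower) without day 0 replicate 1, 7 without day 5 replicate 3, and 0 without day 0 replicate 2 or 3 or day 5 replicate 1, where 2112, 2311 and 3046 genes had an unadjusted p under 0.05 by edgeR. With day 0 replicate 1 as the only day 0 library edgeR called 0 genes, with 1330 at an unadjusted p under 0.05, as did a fit of only the 6 libraries, with 3109, and DESeq2 on all libraries called 1160.

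The comparison of day 7 with day 0 addresses late repair. At day 7 interferon-stimulated genes fell as a list. Tested against other genes by camera, that call was lost with an estimated correlation (adjusted p = 0.748) and made with a preset one (adjusted p = 7.52e-14). Of 19 monocyte and macrophage markers 10 fell and of 28 extracellular matrix genes 5 rose, and neither list was called (fry adjusted p = 0.0795 and 0.421). Oasl1, an interferon-induced antiviral protein, fell 4.67-fold, from 24.4 ± 9.25 to 5.21 ± 1.52 CPM (SD, n = 3), and Fcgr1, a macrophage antibody receptor, 3.53-fold, from 82.2 ± 19.4 to 23.3 ± 1.78 CPM. Postn, a matrix protein of healing tissue, rose 3.55-fold, from 996 ± 141 to 3533 ± 194 CPM, and Tnn from 7.26 ± 2.01 to 58.1 ± 5.48 CPM.

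By edgeR 1208 genes differed, 532 higher and 676 lower at day 7, and 139 and 288 of these by at least 2-fold. Spink7, a protease inhibitor of squamous epithelia, rose by 4.93 ± 0.98 on the log2 scale (edgeR adjusted p = 0.0168) and Prss35, a serine protease family member, by 4.17 ± 0.72 (edgeR adjusted p = 0.0108). Akr1d1, Mest, the heparin-binding growth factor Mdk, and Tdh rose by 3.66 ± 1.02, 2.76 ± 0.62, 2.71 ± 0.49 and 2.70 ± 0.56. Slfn4 fell by 2.99 ± 0.60, Timd4 by 2.84 ± 0.47, Ifit1bl1 by 2.76 ± 0.45 and Cd209g by 2.48 ± 0.37. The class I genes H2-T24 and H2-T10 fell by 2.81 ± 0.43 and 2.51 ± 0.41, from 23.2 and 9.12 CPM in day 0 replicate 1, 68.5 and 34.0 CPM in replicate 2 and 82.3 and 36.0 CPM in replicate 3. Mup17, of a family of near-identical urinary protein genes, fell by 3.69 ± 0.97, but was at 122 CPM in day 0 replicate 2 and at 11.2 and 9.09 CPM in replicates 1 and 3.

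Of 18 interferon-stimulated genes, 15 fell and 3 did not pass, and 18 fell when adjusted over the list alone (fry adjusted p = 0.0129, and adjusted p = 0.748 with an estimated correlation). Besides Oasl1, the chemokine Cxcl10 fell by 2.09 ± 0.42, and Mx1 and Rsad2 by 2.02 ± 0.37 and 2.01 ± 0.36. The list's mean lay at 0.31, -0.25 and -0.07 in the 3 day 0 libraries and at -1.27, -1.70 and -1.48 in the 3 day 7 libraries. Of 19 monocyte and macrophage markers, 10 fell and 9 did not pass, and 14 fell when adjusted over the list alone, with the list not called (fry adjusted p = 0.0795, mixed test adjusted p = 0.000772). Ly6c2 fell by 3.10 ± 0.52, the scavenger receptor Cd163 by 1.72 ± 0.43, Itgam 2.82-fold and Cd68 by 0.80 ± 0.21. Of 12 genes of alternative macrophage activation, Arg1 rose by 1.92 ± 0.49 and Mrc1 fell by 0.95 ± 0.23, and 2 rose and 5 fell when adjusted over the list alone (fry adjusted p = 0.238). Of 18 neutrophil markers, 3 fell, Fpr2, Il1r2 and Csf3r, by 2.06 ± 0.41, 1.20 ± 0.33 and 1.08 ± 0.25, and 5 when adjusted over the list alone (fry adjusted p = 0.421).

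Of 28 extracellular matrix genes, 5 rose and 23 did not pass, also when adjusted over the list alone, and the list was not called (fry adjusted p = 0.421). Besides Postn, Col12a1 rose by 2.25 ± 0.40, P4ha3 by 1.44 ± 0.32 and the collagen Col8a1 by 1.18 ± 0.30, while Col1a1 had 10850 ± 4155 CPM against 16840 ± 1688 and did not pass (edgeR adjusted p = 0.314). Of 18 matrix proteases and inhibitors, 2 rose, Mmp12 by 2.57 ± 0.57 and Mmp11 by 1.98 ± 0.43, and 3 rose and 1 fell when adjusted over the list alone. That list's median was -0.17 and its mean -0.10, while the fry test pointed up (adjusted p = 0.804, mixed test adjusted p = 0.000155). Of 18 complement and coagulation genes, 5 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone (fry adjusted p = 0.266, mixed test adjusted p = 0.000395). The complement genes Cfb and C4b fell by 1.55 ± 0.33 and 1.30 ± 0.33 and F13a1 by 1.19 ± 0.29, and the inhibitor Tfpi2 rose by 1.14 ± 0.20. Of 20 endothelial genes, Angpt2 rose by 0.81 ± 0.15 and the lymphatic marker Lyve1 fell by 1.44 ± 0.25, and 2 rose and 1 fell when adjusted over the list alone. That list's median was -0.01 and its mean 0.04, and the fry test pointed down (adjusted p = 0.923). Of 21 growth factors, Pdgfa rose by 0.50 ± 0.09, while Csf1, a growth factor of macrophages, fell by 1.13 ± 0.21, as did 1 more, and 2 rose and 3 fell when adjusted over the list alone (fry adjusted p = 0.465, mixed test adjusted p = 2.67e-06). The fibroblast markers Gsn and Ly6a fell by 1.41 ± 0.33 and 1.03 ± 0.20. Dusp1 fell by 1.86 ± 0.38 and the chaperone Hsph1 rose by 1.22 ± 0.22.

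The count of 1208 was 2074 without day 7 replicate 1, 291 and 279 without day 0 replicates 2 and 3, and 425 and 288 without day 7 replicates 2 and 3. It was 79 (15 higher, 64 lower) with day 0 replicate 1 as the only day 0 library, 65 in a fit of only the 6 libraries and 2822 by DESeq2. The interferon list was not called without day 0 replicate 1 (fry adjusted p = 0.0613) or without day 7 replicate 2 or 3 (0.0704 and 0.0634). Of the 49 genes named as called, 18 were called with each of the 6 libraries left out in turn, among them Oasl1, Mx1, Rsad2, Fcgr1, Itgam, Timd4, Col12a1, Tnn and Prss35.

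The 3 comparisons between neighbouring times address when changes set in. By edgeR they gave 1, 4 and 1 genes at an adjusted p under 0.05, with 2199, 2586 and 1573 at an unadjusted p under 0.05, where 857 would be due to chance, and DESeq2 gave 470, 532 and 153. From day 1 to day 3, Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, fell 2.51-fold, from 52.8 ± 9.42 to 21.0 ± 2.51 CPM (SD, n = 3, edgeR adjusted p = 0.00434). From day 3 to day 5, Slc16a3 fell 2.65-fold, from 73.6 ± 7.98 to 27.7 ± 5.33 CPM (edgeR adjusted p = 0.0159). Of the next genes, named after their values were seen, the platelet chemokine Pf4 fell by 0.99 ± 0.12 and the gene model Gm14548 by 1.54 ± 0.22 on the log2 scale, and Styk1 rose by 0.93 ± 0.13. From day 5 to day 7, Arntl went from 17.1 ± 2.74 to 32.1 ± 2.60 CPM and did not pass (edgeR adjusted p = 0.0568).

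From day 3 to day 5, 3 lists fell. Of 22 hypoxia and glycolysis genes 1 fell, and 13 when adjusted over the list alone (fry adjusted p = 0.0132, and adjusted p = 0.185 with an estimated correlation). Of 18 neutrophil markers edgeR called 0 over all genes, and 8 fell when adjusted over the list alone (fry adjusted p = 0.0132, and adjusted p = 0.185 with an estimated correlation). Of 21 growth factors edgeR called 0, and 5 fell when adjusted over the list alone (fry adjusted p = 0.0279, and adjusted p = 0.279 with an estimated correlation). The hypoxia list was called with each of the 6 libraries left out in turn. The neutrophil list was not called without day 3 replicate 1 or day 5 replicates 2 and 3 (0.0638, 0.0739 and 0.0602), nor the growth factor list without day 3 replicates 1 and 2 or day 5 replicates 2 and 3 (0.0658, 0.138, 0.0739 and 0.0602). Removal of both hair-rich libraries also ended the neutrophil and growth factor calls (fry adjusted p = 0.0515 and 0.0812). Fry called 0 lists from day 1 to day 3 and from day 5 to day 7, as did camera with an estimated correlation, while the mixed test called 5 and 1 and camera with a preset correlation 9 and 11. Sdf2l1 was not called without day 3 replicate 1 or 3, where edgeR called 0 genes in that comparison (1556 and 1743 at an unadjusted p under 0.05), and the count was 29 without day 1 replicate 3. From day 3 to day 5, edgeR called 0 genes without day 3 replicate 1 or 2 or day 5 replicate 1 or 3 (1818, 1252, 2684 and 2663 at an unadjusted p under 0.05), 1 without day 5 replicate 2 and 25 without day 3 replicate 3. From day 5 to day 7 it called 0 without any of the 3 day 5 libraries or day 7 replicate 3 (1043, 2402, 1108 and 2105 at an unadjusted p under 0.05).

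Over the whole course, 2380 genes changed by edgeR's F test. Of these 2380 genes, 1140 had group means that spanned at least 2-fold. The highest mean fell at day 1 for 514 of these genes, day 0 for 253, day 7 for 183, day 3 for 134 and day 5 for 56. The lowest mean fell at day 7 for 517, day 1 for 238, day 0 for 212, day 5 for 119 and day 3 for 54. Genes with the widest range among those highest at day 1 were Saa2, Csf3, Fgf23 and the neutrophil attractant Cxcl5, with spans of 7.33, 6.61, 6.49 and 6.43 on the log2 scale. Among those highest at day 7 they were Brinp3, Prss35, Spink7 and Sprr2k, with 5.97, 5.24, 4.78 and 4.36. Among those highest at day 3 were Cbln1 and the acute-phase gene Saa3 (5.65 and 5.27), at day 5 the kallikrein Klk14 and Sez6 (4.32 and 4.12), and at day 0 Eno1b and Sult1e1 (6.40 and 5.59), of which Eno1b was present in day 0 replicates 2 and 3 alone. The count of 2380 was 1327 and 1469 without day 0 replicates 2 and 3, 1174 and 1203 without day 1 replicates 1 and 2, 1572 without day 3 replicate 1 and 1428 without day 7 replicate 2. It was 1008 with day 0 replicate 1 as the only day 0 library and 5853 by DESeq2.

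Among the genes followed at every time, Il1b averaged 37.6, 307, 139, 27.8 and 9.61 CPM at day 0, 1, 3, 5 and 7 (edgeR adjusted p over time = 0.0171), with SDs of 42.0, 122, 24.9, 28.6 and 6.92 over 3 libraries each. S100a8 averaged 27.3 ± 17.1, 256 ± 59.7, 202 ± 60.6, 82.1 ± 54.5 and 35.1 ± 38.5 CPM (edgeR adjusted p over time = 0.0291). Arg1 averaged 14.9 ± 3.09, 57.3 ± 27.8, 94.0 ± 29.4, 71.0 ± 24.1 and 56.3 ± 42.8 CPM (0.032), and the macrophage protein Cd68 139 ± 15.7, 183 ± 25.7, 179 ± 22.6, 105 ± 29.8 and 79.6 ± 15.3 CPM (0.00994). Pecam1 of endothelial cells averaged 107 ± 5.56, 144 ± 21.0, 208 ± 25.2, 151 ± 48.9 and 101 ± 14.3 CPM (0.0221). Krt6a did not pass over time (edgeR adjusted p = 0.0836), nor did the collagens Col1a1 and Col3a1 (0.251 and 0.401), Mki67 (0.271), the smooth muscle actin Acta2 (0.148), the chemokine Cxcl2 (0.0805), the collagenase Mmp13 (0.683), the epidermal genes Krt10 and Flg (0.667 and 0.353), Krt16 (0.133), Adipoq of fat cells (0.458) and Acta1 of skeletal muscle (0.0926).

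**Figure D5:**
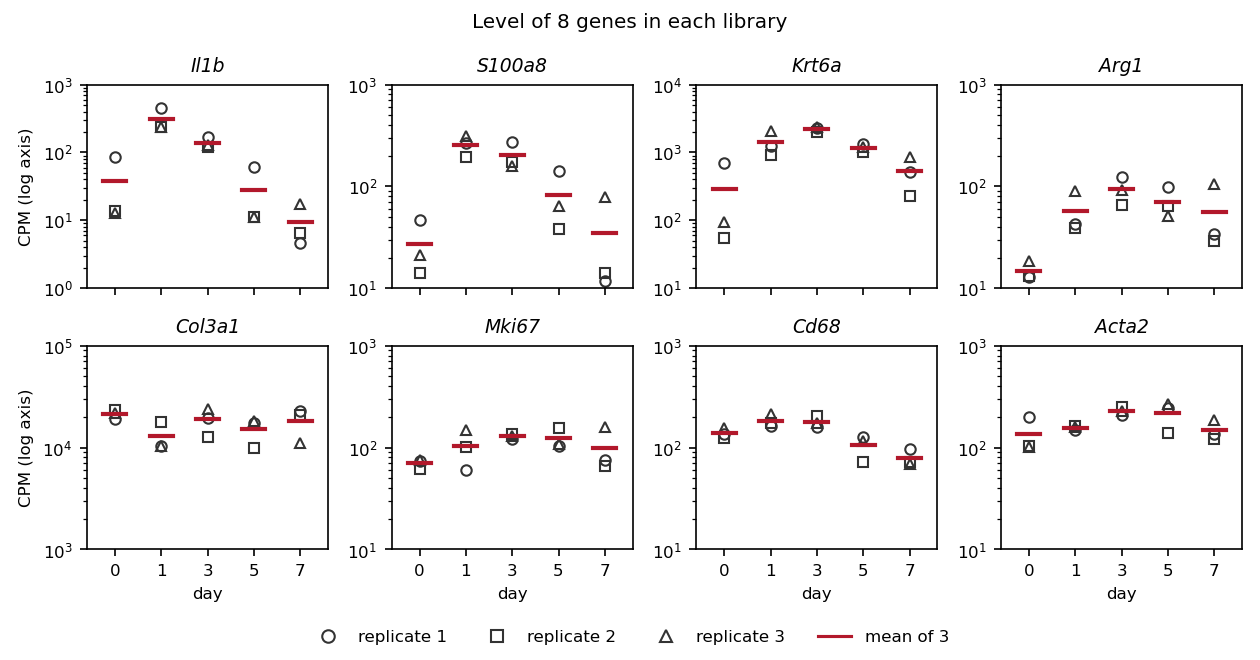
CPM of 8 genes in each of the 15 libraries by day, on log axes, with the replicate number as marker shape and a red line at the mean of the 3 libraries. Il1b and S100a8 average highest at day 1, at 307 and 256 CPM, Krt6a and Arg1 at day 3, at 2220 and 94.0 CPM, and in day 0 replicate 1 Il1b stands at 86.1 CPM against 13.8 and 12.9 CPM in the other day 0 libraries.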

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

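The hair follicle tests below were planned before the result they measure was seen, while the tests of day 0 replicate 1 and of day 0 replicates 2 and 3 were chosen after it was seen. Of the comparisons between neighbouring times, 5 genes named here differ between the effects of 2 times against day 0, by a test of that difference. From day 1 to day 3, Sdf2l1 changed by -1.33 ± 0.13 (SE) on the log2 scale (edgeR adjusted p = 0.00434). From day 3 to day 5, Slc16a3 changed by -1.41 ± 0.16 (edgeR adjusted p = 0.0159), Pf4 by -0.99 ± 0.12 (0.0224), Gm14548 by -1.54 ± 0.22 (0.0415) and Styk1 by 0.93 ± 0.13 (0.0415). Each of these 5 genes lost its call with at least 1 library left out. Entries named as dates instead of genes held up to 0.179% of a library's counts and entered no comparison.

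Hair follicle genes were high in day 5 replicate 2 and day 7 replicate 3. Against the other 13 libraries, 8 pigment genes had a median log2 difference of 4.10 (bounds 3.29 to 4.66), as growing-phase hair follicles in the sampled skin would give. Reads shared between similar hair keratins are argued against as the whole cause, since 8 hair follicle genes without close copies had a median difference of 4.25 (3.71 to 6.09). These 8 genes belong to the hair follicle list by which the 2 libraries stood out. Both sets of bounds are over genes and do not measure the spread between libraries. Growing-phase follicles may therefore account for the pattern, and since the 2 libraries belong to 2 times and each time has 1 such library, wounding time does not separate them. Whether the sampled area or the hair cycle differed was not tested.

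Wound-response genes were high in day 0 replicate 1 against day 0 replicates 2 and 3. A like share of the day 1 rise in immediate early genes and neutrophil markers was taken as the mark of admixture of day 1 RNA alone. Shares were taken on the log2 scale, where admixture gives a share that varies with the size of the rise. Unlike shares therefore cannot decide the question. In this library 8 immediate early genes reached a median of 1.06 and 15 neutrophil markers 0.34 (permutation p = 0.00022 over 100000 resamples of genes between the lists). Genes of a list move together and the values are of 1 library, so the p does not measure the spread between libraries. Admixture is therefore not excluded. A delay before freezing alone was taken to leave the wound-edge keratinocyte genes under 0.5, a premise that was not tested. Under that premise a delay is argued against for this library, since 21 such genes had a median log2 difference of 1.72 (bounds over genes 1.05 to 2.43). A delay that itself raises such genes is not excluded. A mislabelled sample cannot be told apart: the highest over the 4 wounded times of the lower of the shares of rise and fall was 0.72, at day 3, where with genes chosen without the library tested it was 0.56 to 0.67 against 0.62 to 0.99 for the 3 day 3 libraries, while at day 1, 5 and 7 it lay below each library of the time (at most 0.51, 0.50 and 0.39 against at least 0.83, 0.64 and 0.54), which argues against those labels. A first form of this test, on rising genes alone, gave 0.89 at day 5 and met its bound of a wrong label. It was replaced by the form with rise and fall after that result was seen. Genes particular to day 0 replicates 2 and 3 were removed from neither form, so they enter the shares of both.

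Day 0 replicates 2 and 3 differed from the other 13 libraries by at least 4-fold in 42 genes, while at most 1 gene did so for any other of the 105 pairs of libraries, except 205 for the 2 hair-rich libraries. Reads shared between genes and pseudogenes are argued against as the whole cause, since 27 of 101 genes apart by at least 2-fold were pseudogenes or named copies (share 0.27). Among 50 of these genes, 7 neighbouring pairs lay within 2 megabases against a median of 3 in 10000 random sets (permutation p = 0.0477, upper tail alone), so a strain variant against the reference may contribute. That test was written after a first look had shown neighbours, its p is close to the threshold, and 1 of the 7 pairs (Sprr1b and Lce3c) lies in an epidermal gene cluster that responds to wounds. A different transcript index for these 2 libraries, or another origin of the mice, stays open and was not tested.

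The 6 libraries of a comparison make 10 splits into 3 and 3, too few for a share under 0.05. The real split and the highest other gave 1299 and 0 genes for day 1 against day 0, 135 and 1 for day 3, 86 and 0 for day 5, and 1208 and 0 for day 7. Between neighbouring times they gave 1 and 0, 4 and 0, and, from day 5 to day 7, 1 and 805. The split that gave 805 genes sets the 2 hair-rich libraries and day 7 replicate 2 against the rest, which points to a structure of the samples other than time. In that comparison 2 of the 10 splits, the real one included, gave at least as many genes as the real one. Over the whole course, 1 of 100 random splits of the 15 libraries, the real one, gave as many as 2380 genes, and the highest other gave 692. A chance arrangement of 15 independent libraries is therefore excluded at a share under 0.05. The labels do not show that the libraries of a time are independent, so a source other than time that they share is not excluded.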

How the results depend on the processing

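The removal of hair-rich libraries, the hair follicle covariate and the fit on day 0 replicate 1 alone were chosen after the data were seen. Counts of genes are given in the order day 1, 3, 5 and 7 against day 0, then day 3 against 1, 5 against 3 and 7 against 5, then over time. With each library left out in turn, they ranged over 33 to 2411, 0 to 629, 0 to 495, 279 to 2074, 0 to 29, 0 to 25, 0 to 1 and 1174 to 2973, and counts of lists over 3 to 10, 1 to 7, 0 to 2, 0 to 3, 0 to 0, 1 to 4 and 0 to 0. DESeq2 as the test gave 2786, 943, 1160, 2822, 470, 532, 153 and 5853. A 2-fold minimum gave 552 at day 1, 427 at day 7, 2 from day 3 to 5 and 1140 over time, which follows from its construction. No filter gave 71 at day 3 and 9 from day 3 to 5, and the strict filter 11 from day 3 to 5 and 0 from day 5 to 7 (1326 at an unadjusted p under 0.05). A replicate block gave 862, 78 and 27 at day 1, 3 and 5, and 4, 1 and 0 between neighbouring times (1438 at an unadjusted p under 0.05 for the last). Only the 6 libraries compared gave 0 at day 5 (3109 at an unadjusted p under 0.05), 65 at day 7, and 2, 0 and 0 between neighbouring times (2162 and 766 for the last 2), with fewer samples to estimate the spread.

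Without the 2 hair-rich libraries the counts were 3545, 697, 306, 786, 260, 0, 0 and 3828, the 2 counts of 0 with 2082 and 1981 genes at an unadjusted p under 0.05. Without these and day 0 replicate 1 they were 4935, 2163 and 1376 at day 1, 3 and 5 and 5477 over time. With day 0 replicate 1 as the only day 0 library, which is assumed to vary like the other groups, edgeR gave 0, 0, 0 and 79 against day 0 (1324, 1051 and 1330 at an unadjusted p under 0.05 for the first 3) and 1008 over time. The hair follicle covariate gave 306 at day 3, 168 at day 5, 88 from day 1 to 3 and 2 from day 5 to 7. The cause of these changes was not tested. For lists, camera with an estimated correlation gave 0 in each of the comparisons with a fry call, and with a preset correlation 16, 17, 16, 10, 9, 22 and 11. The replicate block gave 5 lists at day 3 and 6 from day 3 to 5, and removal of the hair-rich libraries gave 12, 8, 1 and 1 lists for day 1 and 3 against day 0, day 3 against 1 and day 5 against 3. Other counts stayed within 1.5 times under these settings, as did all under DESeq2 size factors and removal of muscle, fat and blood genes. No named gene changed direction where it was called in the main fit or under the setting. Sign changes of genes called in neither were not counted. The balance at day 5, 36 higher and 50 lower, turned to 63 and 12 without day 5 replicate 2, 253 and 242 without day 0 replicate 1, 4 and 3 without day 5 replicate 3, 15 and 12 with the replicate block, 177 and 129 without the hair-rich libraries and 767 and 609 without these and day 0 replicate 1. At day 7, 532 higher and 676 lower became 33 and 32 with only the 6 libraries, and 214 and 211 or 145 and 143 without day 7 replicate 2 or 3. The replicate block ended the call of the T and NK cell list at day 1 (fry adjusted p = 0.0555), whose adjusted p ranged from 4.39e-06 (camera, preset correlation) to 0.458 (camera, estimated correlation) over its alternatives. Of 21 correlations between libraries of the same number, 10 were over 0.1, and 4 libraries correlated best with their own number.

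Of 178 results for named genes, calls were lost in 1 under DESeq2, 0 under DESeq2 size factors, 31 without a filter, 46 with the replicate block, 102 with only the 6 libraries, 16 without the hair-rich libraries and 7 with the hair follicle covariate, and in 151 of 172 with day 0 replicate 1 as the only day 0 library. With each library left out in turn, calls were lost in 601 of 1068. The totals of 178, 172 and 1068 include results not called in the main fit, which could lose no call. The shares of calls lost are therefore higher than these numbers give. Of the genes named as called, 4 of 60 at day 1, 0 of 28 at day 3, 0 of 25 at day 5 and 18 of 49 at day 7 were called in each of these fits. Each library held at least 38062562 estimated counts, and the effect of a lower depth was not tested.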

Other observations

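The lists and tests in this part were planned, while which of their genes to describe was chosen after the values were seen. At day 7, of 24 Polycomb and chromatin regulators 2 rose, the deacetylase Hdac2 by 0.57 ± 0.14 (SE) and the demethylase Kdm5b by 0.51 ± 0.12 on the log2 scale, also when adjusted over the list alone (fry adjusted p = 0.421, mixed test adjusted p = 0.0105). Of 18 skeletal muscle genes 1 fell, Acta1, by 1.19 ± 0.33, and 3 when adjusted over the list alone (fry adjusted p = 0.238). Of 16 adipocyte markers edgeR called 0, and 6 fell when adjusted over the list alone (fry adjusted p = 0.238). Of 8 erythroid genes edgeR called 0, and 5 fell when adjusted over the list alone (fry adjusted p = 0.421). At day 3, Krt14 was the 1 of 10 basal keratinocyte markers to rise, and 3 rose when adjusted over the list alone (fry adjusted p = 0.126). At day 1, 1 of 19 monocyte and macrophage markers rose, Cd14, by 1.72 ± 0.33, and the list was not called (fry adjusted p = 0.973).

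Retnla, a secreted protein of alternatively activated macrophages, averaged 198 ± 82.1, 11.8 ± 7.12, 8.38 ± 6.58, 14.0 ± 9.23 and 38.5 ± 32.5 CPM at day 0, 1, 3, 5 and 7 (SD, n = 3 each, edgeR adjusted p over time = 0.0306), and in day 0 replicate 1 it was at 106 CPM against 226 and 263 CPM in replicates 2 and 3. Arntl, a core clock gene, averaged 36.0 ± 3.94, 19.5 ± 0.932, 18.4 ± 0.930, 17.1 ± 2.74 and 32.1 ± 2.60 CPM (edgeR adjusted p over time = 0.00121). The hour of sampling is not given in the sources used here.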
